A study of Homo sapiens with 8 samples.

How the data were processed

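RNA was measured by sequencing in 8 libraries from human lung cancer lines, 4 from NCI-H1944 and 4 from NCI-H647. Per the labels' protocols, RNA was isolated on columns with DNase treatment. The NCI-H1944 libraries were made with a stranded kit that selects poly(A) RNA. The NCI-H647 libraries were made with a stranded kit after depletion of ribosomal RNA and were converted for an MGI sequencer. The deposited values are whole-number counts of reads per gene, not normalized, in 1 table per line, and the NCI-H647 table also holds Ensembl IDs, gene types and coordinates. The submitters' processing notes name Trim Galore, Trimmomatic, cutadapt, STAR, featureCounts, HISAT2 and StringTie, and the build GRCh38. Their versions, which of them made which table, the annotation release and the strand setting of the counting are not given in the sources used here. Overlapping genes, antisense genes, readthrough loci and near-identical copies are therefore uncertain.

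Samples were grouped by line and treatment from their titles, and each table column was matched to a sample by name. The NCI-H1944 table lists 46427 genes, 21455 of them at 0 in every library, and the NCI-H647 table lists 61271, with 32964 at 0. Where a symbol was listed more than once (2 entries beyond the first of their symbol in NCI-H1944 and 1232 in NCI-H647), the entry with the highest count stood for it in gene lists and between lines. Totals ran from 38904473 to 43661342 counts per library in NCI-H1944 and from 13358514 to 19550859 in NCI-H647, so low genes are less precise in NCI-H647. Protein-coding genes held 95.6% to 95.9% and 91.9% to 93.5% of counts. Ribosomal RNA genes held 2.34% to 2.74% in NCI-H1944. The Pearson correlation of log2 CPM between replicates, across genes, was from 0.996 to 0.998 in the 4 groups. The first principal component, which separated treated from control libraries, held 64.4% of the variance in NCI-H1944 and 78.6% in NCI-H647. The biological coefficient of variation was 3.99% and 3.54%. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

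Counts were analysed in R 4.3.3. Within each line, genes were kept by edgeR's filterByExpr (version 4.0.16, minimum count 10 and minimum total 15), scaled by TMM factors and compared by edgeR's quasi-likelihood F test of the inhibitor against DMSO. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The lines were fitted apart because their kits and tables differ. The difference between the lines was the interaction term of a joint fit of all 8 libraries on the genes that passed the filter in both lines, out of 32124 shared symbols. Overlap between the lines was set against the product of the numbers called over the number tested, with a two-sided Fisher's exact test. A fold against a group at 0 was computed against a floor of 3 counts over the group, which covers counting error only.

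There were 26 gene lists, 23 written by symbol and 3 by symbol pattern. They were tested with camera (limma 3.58.1) on voom log2 CPM at a preset correlation of 0.01, two-sided, with adjustment over the lists of a line, where at least 5 members were tested. Camera with an estimated correlation and fry were alternatives. Fry asks whether a list's genes move on balance in 1 direction and does not compare the list with other genes. With 4 libraries, an estimated correlation rests on few residual degrees of freedom. The list tests of the difference between the lines were added after the values were seen, and so were 8 further families.

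The genes to be named followed a rule. For each line it took the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1, both treated libraries on the same side of both controls and an approved-style symbol, without histone or ribosomal copies. It also took up to 4 members of each list with the smallest adjusted p, and, whatever their outcome, TTK, CDKN1A, MDM2, IFNB1, IFNL1, CXCL10, CCL5, ISG15, IFIT1, RIGI, IFIH1, MAVS, CGAS, STING1, CDC20 and CCNB1. For the interaction it took the 5 largest differences on each side. Of the list members so taken the text gives a part, picked from them as examples, and some are not reported here. Component genes of the readthrough loci, CNTF and the members of the 8 further families lie outside the rule and were chosen after their values were seen. The sample groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

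The tests were tested on simulated counts drawn from the libraries' means with 200 genes changed. In NCI-H1944, with 16653 genes tested, 58% of genes changed 1.25-fold, 88% at 1.5-fold, 96% at 2-fold and 100% at 4-fold were called, with 7 unchanged genes. In NCI-H647, with 14960 genes, the shares were 44%, 78%, 98% and 98%, with 4 unchanged genes. For the interaction, with 12819 genes, they were 27.9%, 69.2%, 97.8% and 95.5%, with 7 unchanged genes. A simulated raised list of 40 genes was called in both lines with the preset and with the estimated correlation, and an unchanged list was not. Simulated genes were drawn independently of each other and with 1 spread for all genes. The simulation therefore cannot show how the list tests behave on lists of correlated genes. The 200 changed genes were drawn only from those above 1 CPM, so the shares do not hold for lower genes. Far fewer genes changed than were called in the data, so calling and scaling under such broad change were not tested.

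The alternatives were RLE factors, the DESeq2 test (version 1.42.0), no low-count filter, the replicate number as a block, a joint fit of both lines, a test against a 1.5-fold minimum (glmTreat), leaving out each library, and, for the overlap, an unadjusted p under 0.01 or a higher expression minimum. Protein-coding genes alone and thinning of all libraries of a line to the smallest total were chosen after seeing the data. Adjusted p-values named with a tool come from that tool, and all others come from edgeR for genes and camera for lists. A permutation test of 100000 draws was used for the neighbours of raised genes.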

Results

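RNA was sequenced from NCI-H1944 and NCI-H647, established human lung cancer cell lines. Cells were given 100 nM of BAY-1217389, an inhibitor of the spindle checkpoint kinase MPS1, or DMSO for 48 hours, and were collected 24 hours after the drug was washed out. MPS1, the product of TTK, delays anaphase until chromosomes are attached to the spindle, so that its inhibition leads to chromosome missegregation. Each of the 4 groups held 2 libraries. The NCI-H1944 libraries held 39332931 and 38904473 counts after DMSO and 43661342 and 43067647 after the inhibitor. In NCI-H647 the totals were 19550859 and 17243487 after DMSO and 13563037 and 13358514 after the inhibitor. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom from 1.92 to 3.82 over genes, and none was a copy of another. Every value below compares the inhibitor with DMSO, with n = 2 libraries per group. Changes are log2 fold changes ± the standard error of the fit, and levels are counts scaled to library size (CPM) ± SD.

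The comparison in NCI-H1944 asked how expression was altered after a pulse of MPS1 inhibition, in a study titled for RNA sensing and anti-tumour immunity. All 45 tested interferon-stimulated genes rose, with a median fold of 6.56, and 44 of 45 genes of mitosis fell, with a median 1.63-fold decrease. Both lists passed camera's test at a preset correlation, and each had an adjusted p = 0.0543 with an estimated correlation. RIGI and IFIH1, which encode the cytosolic RNA sensors RIG-I and MDA5, rose 8.81-fold and 8.22-fold. The type III interferon genes IFNL1, IFNL2 and IFNL3 had at most 9 counts in a DMSO library and at least 202 in a treated library, and CCL5, a chemokine that attracts T cells, rose 4.42-fold. In edgeR's quasi-likelihood test 2271 of 16738 genes were higher and 2075 lower at an adjusted p under 0.05, which was 26.0% of the genes tested. Of these, 521 rose and 38 fell at least 2-fold, and 242 rose and 13 fell at least 4-fold. With no low-count filter 1319 were higher and 1006 lower, and 385 and 42 passed against a 1.5-fold minimum.

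Within the interferon-stimulated list, IFIT1, whose product binds foreign 5' RNA ends, rose from 40.6 ± 0.342 to 645 ± 1.70 CPM (log2 3.99 ± 0.03, adjusted p = 1.56e-20). MX1 and MX2, dynamin-like antiviral GTPases, rose by 4.03 ± 0.03 and 6.96 ± 0.10, and ISG15, a ubiquitin-like modifier, rose by 2.86 ± 0.03. RSAD2 (viperin) and its genomic neighbour CMPK2, a nucleotide kinase, rose by 4.82 ± 0.08 and 5.17 ± 0.08. All 45 members also passed when adjusted over the list alone. The list as a whole rose in camera's test at a preset correlation (adjusted p = 4.37e-88), with an adjusted p = 0.0543 with an estimated correlation. In camera with an estimated correlation 0 of the 26 lists passed in this line, 11 had an unadjusted p under 0.05, and fry called 23. The adjusted p with an estimated correlation is given below beside that of each list that passed at the preset one.

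Of 24 tested interferons, chemokines and cytokines 21 rose and none fell, with 22 higher when adjusted over the list alone (median 1.53, adjusted p = 4.85e-19, and adjusted p = 0.0543 with an estimated correlation). The median was the same with the 3 members at 0 in a group set to their bound. IFNL1, a type III interferon, had 5 and 2 counts after DMSO and 241 and 309 after the inhibitor (log2 6.11 ± 0.33). IFNL2 had 0 and 0 against 202 and 270 counts, at least 143-fold higher, and IFNL3 had 0 and 9 against 239 and 302. IFNL2 and IFNL3 are near-identical, so the division of reads between them is uncertain. IFNB1, the type I interferon, had 0 and 0 against 26 and 22 counts, at least 14.5-fold higher (adjusted p = 0.000319). CXCL10, a T cell chemokine, had 0 and 0 against 72 and 66 counts, at least 41.8-fold higher. These floors are 3 counts over the group and cover counting error only. CCL5 rose from 24.3 to 107 CPM (log2 2.14 ± 0.06), TNFSF10, the death ligand TRAIL, by 3.45 ± 0.11, and IL6 by 2.02 ± 0.10.

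Among 20 genes of RNA sensing 13 rose and 1 fell, and 16 rose and 1 fell when adjusted over the list alone (median 0.77, adjusted p = 2.32e-15, and adjusted p = 0.0636 with an estimated correlation). RIGI (NCBI gene 23586) rose from 47.9 ± 0.328 to 422 ± 9.55 CPM (log2 3.14 ± 0.04, adjusted p = 6.53e-19). IFIH1 rose from 19.8 to 163 CPM (log2 3.04 ± 0.05), and PNPT1, a mitochondrial RNA exonuclease, rose by 2.32 ± 0.04. MAVS, the adaptor that both sensors signal through, fell (log2 -0.28 ± 0.04, adjusted p = 5.05e-05). Of 15 genes of DNA sensing 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (median 0.11, adjusted p = 0.000744, and adjusted p = 0.128 with an estimated correlation). STING1, which relays the signal of cGAS, rose by 1.01 ± 0.08, IFI16 by 1.83 ± 0.03 and TREX1, a DNA exonuclease, by 2.55 ± 0.14. CGAS rose by 0.28 ± 0.08 (adjusted p = 0.0219), and this call was lost without the first DMSO library (0.138), without the first treated library (0.204) and with no low-count filter (0.126). Its adjusted p ranged from 0.00445 to 1 over the alternatives, the highest against a 1.5-fold minimum.

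The list of antigen presentation by MHC class I rose in 23 of 26 genes, and in 24 when adjusted over the list alone (median 1.09, adjusted p = 2.55e-28, and adjusted p = 0.110 with an estimated correlation). It also held CD274, PDCD1LG2, MICA, MICB, ULBP1 and ULBP2, which encode surface ligands and not parts of class I presentation. HLA-B, a class I heavy chain, rose 3.94-fold, TAP1, a subunit of the peptide transporter, 4.61-fold, and the light chain gene B2M 2.86-fold. NF-kB targets rose in 19 of 20 genes, and in 20 when adjusted over the list alone (median 0.57, adjusted p = 2.67e-18, and adjusted p = 0.0543 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose by 1.39 ± 0.04, the feedback regulator TNFAIP3 by 1.07 ± 0.06 and SOD2, the mitochondrial superoxide dismutase, by 0.74 ± 0.03. Secreted factors of senescence rose in 18 of 23 genes and fell in 1, with the same counts adjusted over the list alone (median 0.48, adjusted p = 3.87e-15, and adjusted p = 0.0543 with an estimated correlation). IGFBP6, which binds insulin-like growth factors, rose by 0.97 ± 0.03. Of 25 apoptosis regulators 16 rose and none fell, also when adjusted over the list alone (median 0.35, adjusted p = 7.41e-10, and adjusted p = 0.0636 with an estimated correlation). In both lines that list pools genes that promote and genes that inhibit apoptosis, so its direction does not tell their balance. CASP1, the inflammasome protease, rose 4.48-fold. YAP targets rose in 12 of 15 genes, and in 13 when adjusted over the list alone (median 0.38, adjusted p = 1.52e-09, and adjusted p = 0.0638 with an estimated correlation), with the ecto-5'-nucleotidase NT5E higher by 1.05 ± 0.04.

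TTK, the gene of the drug's target, fell 1.63-fold (log2 -0.71 ± 0.08, adjusted p = 9.03e-06). CCNB1 (cyclin B1) fell 1.90-fold, CDC20, an activator of the anaphase-promoting complex, 1.93-fold, and PLK1, a mitotic kinase, 2.07-fold. The mitosis list fell in 44 of 45 genes, also when adjusted over the list alone (median -0.71, adjusted p = 2.01e-38, and adjusted p = 0.0543 with an estimated correlation). DNA replication and G1/S genes fell in 20 of 42, also when adjusted over the list alone (median -0.21, adjusted p = 1.55e-06, and adjusted p = 0.0654 with an estimated correlation). TYMS (thymidylate synthase) fell by 0.35 ± 0.04 on the log2 scale. The p53 target list was not called, with 10 genes higher and 7 lower of 32, and 12 and 7 when adjusted over the list alone (median 0.09, adjusted p = 0.0888). It was called only without the first treated library (adjusted p = 0.0403) and in the fry test (0.00808), and was at most 0.336 over its alternatives. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 740 to 796 CPM (log2 0.11 ± 0.02), GDF15, a stress cytokine, from 745 to 872 CPM, and MDM2, which degrades p53, by 0.20 ± 0.03. Cell-cycle inhibitors were not called as a list, with 2 genes higher and 2 lower of 11 by both adjustments, adjusted over all genes or adjusted over the list alone (median -0.12, adjusted p = 0.295).

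Cytosolic ribosomal protein genes fell in 74 of 77, and in 76 when adjusted over the list alone, by a small amount each (median -0.19, adjusted p = 2.63e-46, and adjusted p = 0.0543 with an estimated correlation). RPL3 fell by 0.49 ± 0.02 on the log2 scale. NRF2 targets fell in 16 of 25 genes and rose in 2, with 17 lower and 2 higher when adjusted over the list alone (median -0.11, adjusted p = 1.41e-07, and adjusted p = 0.0654 with an estimated correlation). TKT (transketolase), of the pentose phosphate pathway, was among them (log2 -0.28 ± 0.02). Mitochondrially encoded mRNAs fell in 6 of 13 and rose in 2, with 7 and 3 when adjusted over the list alone (median -0.06, adjusted p = 0.00148, and adjusted p = 0.343 with an estimated correlation), and their share of all counts was 5.16% and 5.13% after DMSO and 4.95% and 4.90% after the inhibitor. Replication-dependent histone genes rose in 14 of 36 and none fell, with 15 higher when adjusted over the list alone (median 0.40, adjusted p = 4.39e-06, and adjusted p = 0.154 with an estimated correlation). H2BC12 and H2AC18 rose by 0.39 ± 0.04 and 0.78 ± 0.06. Their mRNAs lack poly(A) tails, these libraries were made by poly(A) selection, and the near-identical copies share reads.

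Epithelial and mesenchymal state genes rose in 11 of 20 and fell in 1, with 14 and 1 when adjusted over the list alone (median 0.29, adjusted p = 1.44e-05, and adjusted p = 0.154 with an estimated correlation). That list pools markers of both states, so its direction does not tell a shift towards either. Cholesterol synthesis genes fell in 9 of 24 and rose in 3, with 12 and 3 when adjusted over the list alone (median -0.09, adjusted p = 0.0368, and adjusted p = 0.193 with an estimated correlation). Lung and squamous lineage genes rose in 4 of 12, also when adjusted over the list alone (median 0.21, adjusted p = 0.0443, and adjusted p = 0.212 with an estimated correlation). As signs of other cell types, leukocyte and erythroid markers rose in 4 of 8 tested genes and fibroblast and endothelial markers in 5 of 7, with the same counts adjusted over the list alone. Their medians were 1.03 (adjusted p = 0.00549, and adjusted p = 0.193 with an estimated correlation) and 0.59 (adjusted p = 0.00702, and adjusted p = 0.164 with an estimated correlation). CD68, a lysosomal protein abundant in macrophages, rose 2.30-fold. The other leukocyte and erythroid markers called were low. HBA1 had 22 and 18 counts after DMSO and 56 and 55 after the inhibitor, HBA2 30 and 25 against 77 and 65. LYZ had 0 and 5 against 17 and 33, so that list's median rests largely on genes near the floor. The cholesterol call was lost without the first DMSO library (adjusted p = 0.223), the second (0.107) or the second treated library (0.0634), and the fibroblast call without the first (0.0971) or second DMSO library (0.0655). The lung lineage call was lost without any of the 4 libraries, with an adjusted p of 0.272 and 0.275 without either DMSO library and 0.0600 and 0.0607 without either treated library. Not called were heat-shock chaperones (5 higher and 4 lower of 20, or 5 and 5 adjusted over the list alone, median 0.03, adjusted p = 0.971) and lysosome and autophagy genes (6 higher of 29 by both adjustments, median 0.03, adjusted p = 0.0962). Hypoxia and glycolysis genes were not called either (6 higher and 3 lower of 21, or 7 and 3 adjusted over the list alone, median 0.06, adjusted p = 0.0784). For the integrated stress response and unfolded protein response 9 genes rose and 11 fell of 30 by both adjustments (adjusted p = 0.472). That list's median was -0.02 and its test pointed down, while its mean was 0.03.

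The 8 largest rises that met the naming rule were IFNL2, MX2, IFNL1, SLC15A3, IFNL3, NEXN, CMPK2 and RSAD2. SLC15A3, a lysosomal transporter of histidine and small peptides, rose by 5.78 ± 0.25, and NEXN, an actin-binding protein gene, by 5.22 ± 0.26. SLC15A3 had 5 and 6 counts after DMSO and 345 and 332 after the inhibitor. NEXN had 16 and 5 against 464 and 408, and with so few control counts its fold is imprecise. The largest falls by the same rule were in COMMD3-BMI1, ACO1, PRR11, PHOSPHO2-KLHL23, MSH5-SAPCD1, RPL36A-HNRNPH2, AKNA and PLK1. ACO1 (NCBI gene 48), which encodes the iron-responsive cytosolic aconitase, fell 2.73-fold, from 114 ± 0.0736 to 42 ± 0.235 CPM (adjusted p = 1.04e-13). PRR11 fell 2.30-fold and AKNA 2.11-fold. COMMD3-BMI1 had 369 and 385 counts after DMSO and 19 and 14 after the inhibitor, while its component genes COMMD3 and BMI1 changed by 0.07 ± 0.07 (adjusted p = 0.528) and 0.14 ± 0.04 (adjusted p = 0.0244). The 4 hyphenated names are readthrough loci that share exons with their component genes, so their counts are uncertain. RPL36A-HNRNPH2 (adjusted p = 0.00497) was not called by DESeq2 (0.227) or with no low-count filter (0.207), nor MSH5-SAPCD1 with no filter (0.0521). Their lowest adjusted p over the alternatives were 2.13e-14 and 1.07e-12.

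**Figure D1:**
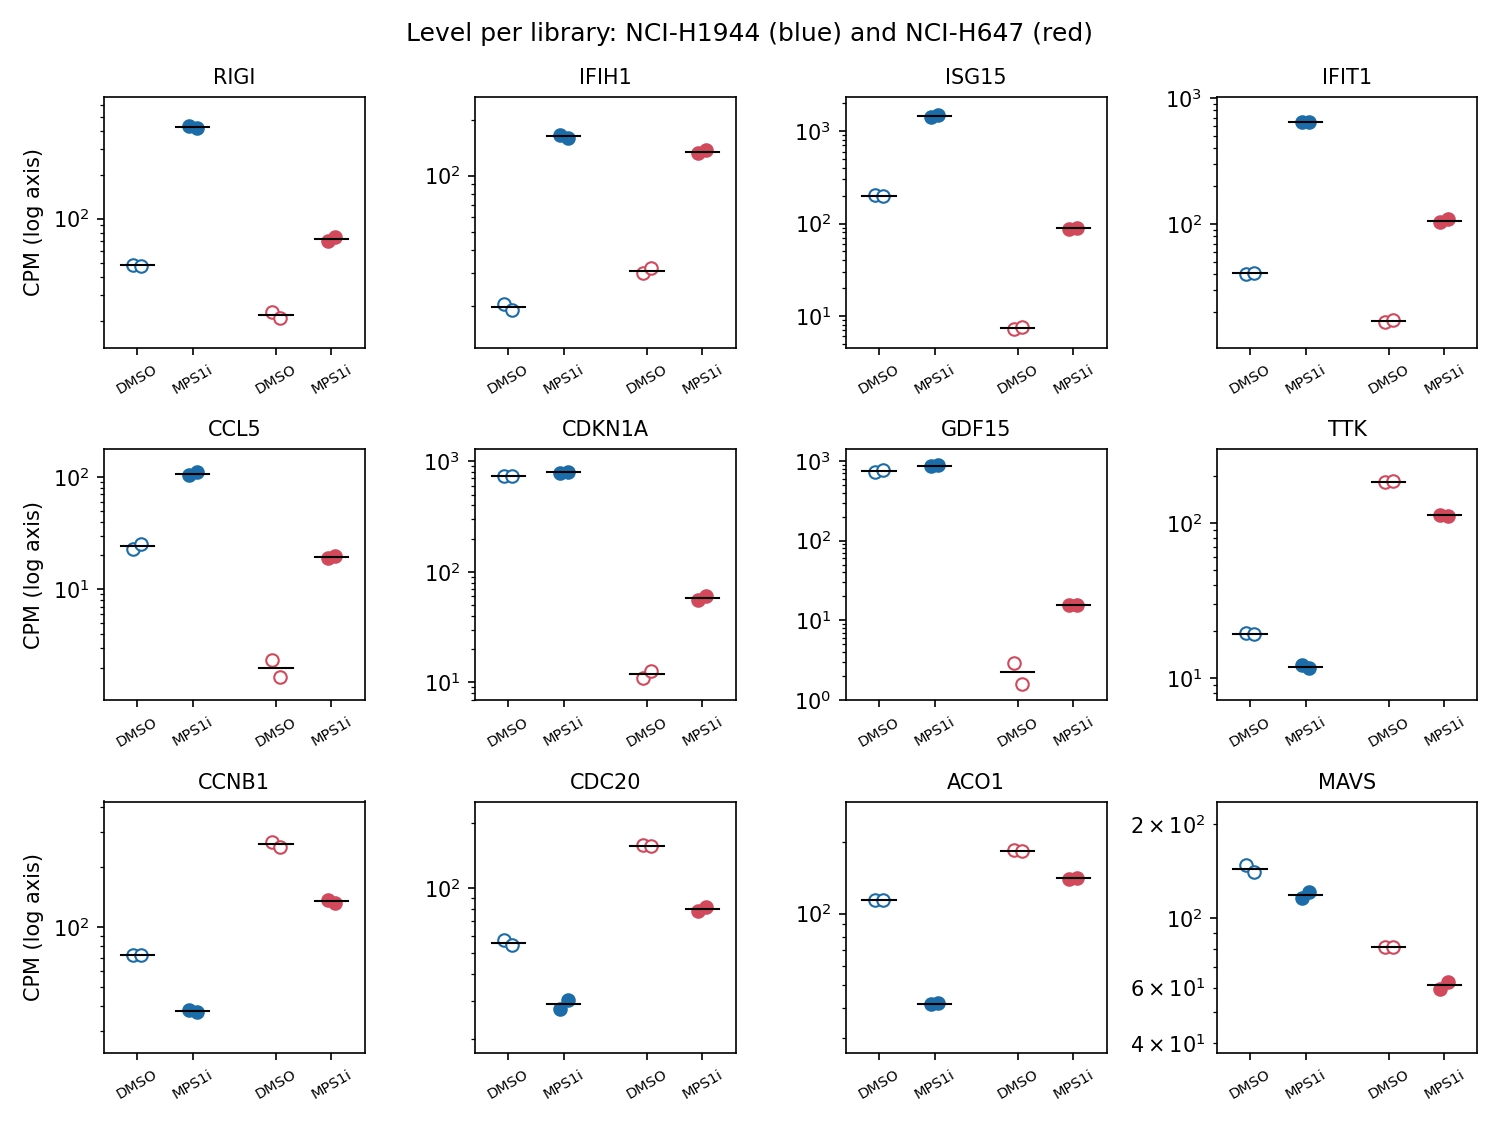
CPM on a log axis in each of the 8 libraries for 12 genes, with open points for DMSO, filled points for the MPS1 inhibitor and a bar at each group's mean (n = 2). In NCI-H1944 RIGI rises from 47.9 to 422 CPM and ACO1 falls from 114 to 42, and in NCI-H647 CDKN1A rises from 11.9 to 58.2.

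The comparison in NCI-H647 put the same question to a second lung cancer line. All 45 interferon-stimulated genes rose, with a median fold of 3.82, and all 45 mitosis genes fell, with a median 1.65-fold decrease. Both lists passed at the preset correlation, with an adjusted p = 0.0804 and an adjusted p = 0.0963 with an estimated correlation. The largest rises among cytokines were in CSF2 (GM-CSF), 51.9-fold, and in IL1B, the inflammatory cytokine interleukin-1 beta, 24.3-fold. CSF2 had 12 and 3 counts after DMSO and 289 and 311 after the inhibitor, so its fold is imprecise. CDKN1A rose 4.92-fold. Replication-dependent histone genes fell in 57 of 61, with a median 3.34-fold decrease (adjusted p = 0.142 with an estimated correlation). In edgeR's quasi-likelihood test 4114 of 15049 genes were higher and 4070 lower at an adjusted p under 0.05, which was 54.4% of the genes tested. Of these, 843 rose and 329 fell at least 2-fold, and 217 rose and 25 fell at least 4-fold. DESeq2 called 2122 higher and 2573 lower, and 792 and 464 passed against a 1.5-fold minimum.

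ISG15 rose from 7.40 to 88.7 CPM (log2 3.58 ± 0.06, adjusted p = 1.96e-15). MX1 rose by 4.36 ± 0.04, IFI27 and IFI6, mitochondrial proteins induced by interferon, by 4.79 ± 0.09 and 3.70 ± 0.05, and TRIM22, an antiviral ubiquitin ligase, by 4.51 ± 0.20. IFIT1 rose by 2.66 ± 0.06. The interferon-stimulated list had all 45 members higher when adjusted over the list alone too (median 1.94, adjusted p = 2.58e-37, and adjusted p = 0.0804 with an estimated correlation). In camera with an estimated correlation 0 of 24 lists passed, 9 had an unadjusted p under 0.05, and fry called 21. RNA sensing genes rose in 11 of 20 and fell in 2, also when adjusted over the list alone (median 0.23, adjusted p = 0.000332, and adjusted p = 0.174 with an estimated correlation). RIGI rose from 22 to 72.6 CPM (log2 1.72 ± 0.06, adjusted p = 2.38e-12) and IFIH1 by 2.12 ± 0.06, and MAVS fell (log2 -0.41 ± 0.05, adjusted p = 8.99e-06). RIGI lies on chromosome 9 from 32455302 to 32526208 on the minus strand of GRCh38 in this line's table. DNA sensing was not called as a list, with 7 genes higher and 5 lower of 15 by both adjustments, over all genes or adjusted over the list alone (median 0.18, adjusted p = 0.403). CGAS rose by 0.33 ± 0.07 (adjusted p = 0.000734), STING1 by 0.27 ± 0.06 (adjusted p = 0.00114) and IFI16 by 0.57 ± 0.04. DESeq2 called neither CGAS (0.0906) nor STING1 (0.153), and over the alternatives their adjusted p ranged from 2.99e-06 and 4.98e-05 to 1, the highest against a 1.5-fold minimum.

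Interferons, chemokines and cytokines rose in 23 of 25 tested genes and fell in 1, also when adjusted over the list alone (median 1.86, adjusted p = 4.55e-17, and adjusted p = 0.0804 with an estimated correlation). IL1B rose from 23.3 ± 0.723 to 566 ± 11.8 CPM (log2 4.60 ± 0.05, adjusted p = 2.06e-18). CSF2 and CSF3, colony-stimulating factors of granulocytes and macrophages, rose by 5.70 ± 0.23 and 3.48 ± 0.07. The neutrophil chemokine gene CXCL8 rose from 519 to 4701 CPM, CCL20, a chemokine for dendritic cells and lymphocytes, 8.86-fold and CCL5 9.59-fold. CXCL10 had 1 and 2 counts after DMSO and 24 and 19 after the inhibitor (log2 4.12 ± 0.54). IFNB1, at 0 and 0 against 1 and 2 counts, and IFNL1, at 0 and 0 against 1 and 0, were under the count minimum and were not tested. NF-kB targets rose in 18 of 20 genes and fell in 1, also when adjusted over the list alone (median 0.91, adjusted p = 5.43e-13, and adjusted p = 0.0804 with an estimated correlation). SOD2 rose by 1.95 ± 0.03 and BIRC3 by 1.43 ± 0.04. The MHC class I presentation list, which holds the same surface ligands, rose in 20 of 25 genes, also when adjusted over the list alone (median 0.59, adjusted p = 1.19e-09, and adjusted p = 0.0804 with an estimated correlation). HLA-B was higher by 1.93 ± 0.05, TAP1 by 1.94 ± 0.08 and B2M by 0.89 ± 0.03.

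TTK fell 1.65-fold (log2 -0.72 ± 0.04, adjusted p = 2.39e-09), CCNB1 1.93-fold and ASPM, which organises spindle poles, 2.48-fold. CDC20 fell by 0.97 ± 0.05 and TOP2A, the mitotic topoisomerase, by 0.91 ± 0.03 on the log2 scale. The mitosis list fell in 45 of 45 genes, also when adjusted over the list alone (median -0.72, adjusted p = 1.79e-27, and adjusted p = 0.0963 with an estimated correlation). DNA replication genes fell in 39 of 42 and rose in 1, also when adjusted over the list alone (median -0.75, adjusted p = 3.30e-15, and adjusted p = 0.0804 with an estimated correlation). TYMS fell by 0.91 ± 0.05 on the log2 scale. The histone list fell (median -1.74, adjusted p = 2.62e-42, and adjusted p = 0.142 with an estimated correlation), with 58 of 61 lower when adjusted over the list alone. H1-5, a linker histone, fell 4.26-fold and H3C2 4.85-fold. These libraries were made by depletion of ribosomal RNA, which keeps RNA without poly(A) tails. CDKN1A rose from 11.9 ± 1.15 to 58.2 ± 3.06 CPM (log2 2.30 ± 0.07, adjusted p = 1.27e-12) and GDF15 from 2.23 to 15.7 CPM. MDM2 was measured at 0.02 ± 0.05 (adjusted p = 0.747). The p53 list was not called, with 12 genes higher and 7 lower of 29, or 12 and 8 adjusted over the list alone (median 0.15, adjusted p = 0.163). Neither was the list of cell-cycle inhibitors (4 higher and 3 lower of 11 by both adjustments, median 0.04, adjusted p = 0.466). The fry test called both lists as higher (adjusted p = 0.00192 for p53 targets and 0.0213 for cell-cycle inhibitors).

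Secreted factors of senescence rose in 21 of 26 genes and fell in 2, also when adjusted over the list alone (median 1.09, adjusted p = 5.05e-10, and adjusted p = 0.0804 with an estimated correlation). INHBA, an activin subunit, rose 10.7-fold and MMP1, an interstitial collagenase, 35.3-fold. The integrated stress and unfolded protein responses rose in 19 of 29 genes and fell in 6, also when adjusted over the list alone (median 0.26, adjusted p = 0.00194, and adjusted p = 0.142 with an estimated correlation). PPP1R15A, which directs dephosphorylation of eIF2-alpha, rose from 24.3 to 97.1 CPM and DNAJB9, a chaperone of the endoplasmic reticulum, rose by 1.33 ± 0.07. Lysosome and autophagy genes rose in 21 of 29, and in 22 when adjusted over the list alone (median 0.28, adjusted p = 1.03e-06, and adjusted p = 0.0963 with an estimated correlation), with GABARAPL1, an autophagosome protein, higher 2.29-fold and CTSL, a lysosomal protease, by 0.87 ± 0.06. Apoptosis regulators rose in 17 of 23 genes and fell in 4, also when adjusted over the list alone (median 0.35, adjusted p = 8.06e-05, and adjusted p = 0.121 with an estimated correlation). PMAIP1 (NOXA), a pro-apoptotic BH3-only protein, rose 3.12-fold. NRF2 targets fell in 20 of 25 genes and rose in 4, also when adjusted over the list alone (median -0.39, adjusted p = 1.54e-07, and adjusted p = 0.149 with an estimated correlation). AKR1B10, an aldo-keto reductase, fell 3.63-fold, NQO1, a quinone reductase, fell by 0.68 ± 0.03 and TKT by 0.82 ± 0.03 on the log2 scale. Ribosomal protein genes fell in 73 of 77 and rose in 1, also when adjusted over the list alone (median -0.40, adjusted p = 6.26e-27, and adjusted p = 0.142 with an estimated correlation), with RPL3 lower 2.06-fold.

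Hypoxia and glycolysis genes rose in 12 of 21 and fell in 5, also when adjusted over the list alone (median 0.25, adjusted p = 0.0416, and adjusted p = 0.379 with an estimated correlation). This call was lost without the first treated library (adjusted p = 0.0637). Not called were heat-shock chaperones (9 higher and 6 lower of 19, or 10 and 6 adjusted over the list alone, median 0.13, adjusted p = 0.708) and cholesterol synthesis (4 higher and 11 lower of 24, or 4 and 12 adjusted over the list alone, median -0.17, adjusted p = 0.136). YAP targets (6 higher and 5 lower of 16 by both adjustments, median 0.02, adjusted p = 0.586) and lung and squamous lineage genes (3 higher of 7 by both, median 0.38, adjusted p = 0.163) were not called. Epithelial and mesenchymal state genes were not called either (9 higher and 5 lower of 21, or 10 and 5 adjusted over the list alone, median 0.08, adjusted p = 0.415). Fibroblast and endothelial markers had 1 gene higher and 3 lower of 10 by both adjustments (adjusted p = 0.708), and their median was 0.02 while the test pointed down. Of 3 tested leukocyte and erythroid markers, too few for a list test, 2 were higher by both adjustments, CD68 by 0.59 ± 0.04. Mitochondrially encoded mRNAs were not analysed here. The share of counts from RN7SK, RN7SL1 and RN7SL2, abundant transcripts without poly(A) tails, was 3.90% and 3.39% after DMSO and 4.61% and 4.43% after the inhibitor.

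The largest rises by the naming rule were in ARL2-SNX15, PI3, CSF2, MMP1, IFI27, IL1B, SERPINB2 and TRIM22. PI3, the elastase inhibitor elafin, had 3 and 0 counts after DMSO and 183 and 190 after the inhibitor (log2 7.23 ± 0.34), and SERPINB2, the plasminogen activator inhibitor PAI-2, rose 23.3-fold. The readthrough locus ARL2-SNX15 had 0 and 0 against 58 and 106 counts, at least 72.4-fold higher, while its component genes ARL2 and SNX15 fell by 0.42 ± 0.05 and 0.51 ± 0.21 on the log2 scale. The largest falls by the same rule were in PWAR5 (log2 -1.91 ± 0.33), AKR1B10, SYT15B (-1.72 ± 0.31), NHSL2 (-1.69 ± 0.10), SFXN2 (-1.66 ± 0.18), ITGBL1 (-1.66 ± 0.23), TMEM215 (-1.64 ± 0.32) and MAP2K6 (-1.63 ± 0.14). The rule leaves out histone genes, of which H3C2 and H1-5, for example, fell by more (4.85-fold and 4.26-fold). SFXN2 is a mitochondrial carrier, and MAP2K6 is a kinase that activates p38.

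**Figure D2:**
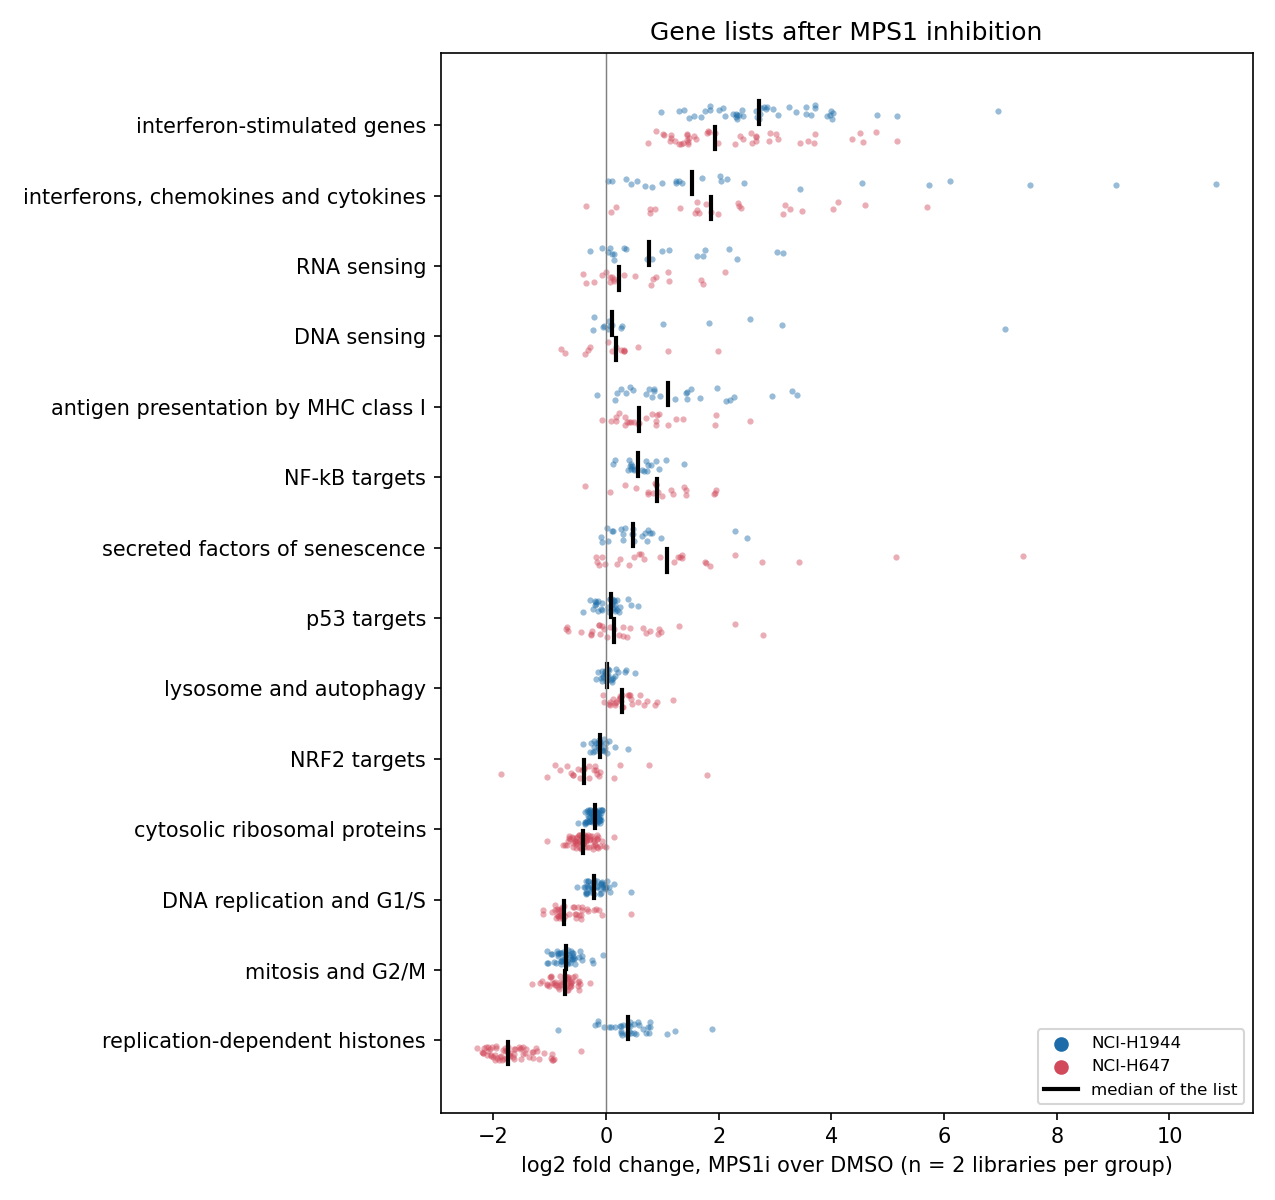
Log2 fold change (MPS1 inhibitor over DMSO, n = 2 libraries per group) of each tested member of 14 gene lists in both lines, 1 point per gene, with a bar at the median. The interferon-stimulated medians are 2.71 in NCI-H1944 and 1.94 in NCI-H647, and the histone medians are 0.40 and -1.74.

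The difference between the lines was tested as an interaction, the effect in NCI-H1944 minus that in NCI-H647, over 12883 genes tested in both. The interferon response was larger in NCI-H1944: 29 of 45 interferon-stimulated genes had the larger effect there and 8 in NCI-H647. RIGI (difference 1.42), IFIH1 (0.92) and MX2 (4.29) were among those with the larger effect in NCI-H1944, and ISG15 (-0.72), MX1 (-0.34) and IFI27 (-2.48) among those with the larger effect in NCI-H647. IL1B (-4.25), CXCL8 (-1.14), CDKN1A (-2.19) and GDF15 (-2.56) had the higher log2 change in NCI-H647, while the p53 target list, which holds CDKN1A and GDF15, showed no called difference (median -0.04, adjusted p = 0.201). CDKN1A and GDF15 started from far lower levels in NCI-H647. They reached 58.2 and 15.7 CPM there after the inhibitor, against 740 and 745 CPM after DMSO in NCI-H1944. In edgeR's quasi-likelihood test the log2 change of 2663 genes was higher in NCI-H1944 and that of 2459 higher in NCI-H647 at an adjusted p under 0.05, falls included. The lines differ in library kit and count table, and such differences cancel in the interaction only as far as they act alike on treated and control libraries.

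As lists, interferon-stimulated genes (median difference 0.58, adjusted p = 2.69e-08) and DNA replication (0.51, adjusted p = 5.21e-11) lay above 0, also with an estimated correlation (adjusted p = 0.0442 and 0.0295 with an estimated correlation). The remaining calls held at the preset correlation only. RNA sensing (0.20, adjusted p = 6.51e-05, and adjusted p = 0.0559 with an estimated correlation), MHC class I presentation (0.40, 2.34e-05, and adjusted p = 0.130 with an estimated correlation) and histones (1.95, 2.10e-19, and adjusted p = 0.0559 with an estimated correlation) were above 0. DNA sensing was above 0 as well (0.50, 0.00109, and adjusted p = 0.0559 with an estimated correlation), although the list's own medians, 0.11 in NCI-H1944 and 0.18 in NCI-H647, lay the other way. Ribosomal proteins (0.19, 1.04e-13, and adjusted p = 0.101 with an estimated correlation) and NRF2 targets (0.22, 8.86e-07, and adjusted p = 0.0559 with an estimated correlation) were above 0, having fallen by more in NCI-H647. YAP targets (0.21, 0.00101, and adjusted p = 0.0559 with an estimated correlation) and epithelial and mesenchymal state genes (0.32, 0.0341, and adjusted p = 0.118 with an estimated correlation) were also above 0.

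Below 0 were cytokines (-0.35, adjusted p = 0.0289, and adjusted p = 0.113 with an estimated correlation), NF-kB targets (-0.32, 3.86e-05, and adjusted p = 0.0509 with an estimated correlation) and secreted factors of senescence (-0.41, 0.000209, and adjusted p = 0.0509 with an estimated correlation). The stress responses (-0.31, 8.95e-05) and lysosome genes (-0.24, 7.78e-07) were below 0 too, each with an adjusted p = 0.0509 with an estimated correlation, as were cell-cycle inhibitors (-0.13, 0.0287, and adjusted p = 0.377 with an estimated correlation). Mitosis genes showed no called difference (0.04, adjusted p = 0.165), with 9 genes higher in NCI-H1944 and 6 in NCI-H647. Nor did p53 targets (-0.04, 0.201), heat-shock chaperones (-0.07, 0.443), cholesterol synthesis (0.07, 0.443), hypoxia (-0.04, 0.144), lung lineage (-0.02, 0.964), apoptosis regulators (-0.04, 0.963) and fibroblast markers (0.38, 0.356).

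The 5 genes named on each side were those with the largest fitted differences, but fitted values of genes at 0 in a group depend on the prior count, so that their rank is uncertain and counts are given. On the NCI-H1944 side GBP5, an interferon-induced GTPase, had 0 and 0 against 38 and 65 counts there, at least 31.3-fold higher, and 251 and 238 against 525 and 563 in NCI-H647. AIM2, a DNA sensor of inflammasomes, had 0 and 0 against 18 and 17, at least 10.6-fold higher, and 169 and 120 against 236 and 235. IL7R, the interleukin-7 receptor, had 0 and 0 against 23 and 16, at least 11.8-fold higher, and 1192 and 1122 against 819 and 805. GPSM3, a regulator of G protein signalling, had 0 and 0 against 19 and 22, at least 12.4-fold higher, and 224 and 200 against 151 and 143, and the readthrough locus ZFP91-CNTF had 0 and 0 against 75 and 97, at least 52.2-fold higher, and 37 and 55 against 241 and 115. On the NCI-H647 side LCN2, the iron-trapping protein lipocalin 2, had 731 and 723 against 1322 and 1329 counts in NCI-H1944 and 1 and 0 against 30 and 33 in NCI-H647. PI3 had 278 and 323 against 576 and 617 in NCI-H1944. BHLHB9 had 84 and 119 against 0 and 0 in NCI-H1944, at least 74.4-fold lower, and 111 and 110 against 52 and 48 in NCI-H647. This switch to 0 in both treated libraries is uncertain, since how reads of overlapping loci were assigned is not given in the sources used here. The readthrough loci COMMD3-BMI1, with 0 and 27 against 39 and 71 counts in NCI-H647, and ARL2-SNX15, with 71 and 65 against 87 and 99 in NCI-H1944, completed that side. These counts are not scaled to library size, and the treated NCI-H647 libraries were shallower than the DMSO ones. Scaled, in the joint fit, the log2 change in NCI-H647 was 1.55 for GBP5, 1.11 for AIM2, -0.11 for IL7R, -0.13 for GPSM3, 2.34 for ZFP91-CNTF and -0.74 for BHLHB9.

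The overlap of the responses was larger than chance in both directions. Of the 12883 genes 1221 rose in both lines, against 560 for independent lists (two-sided Fisher's exact test, p = 2.71e-255), and 1257 fell in both, against 566 (p = 3.56e-278). In opposite directions, 230 genes rose in NCI-H1944 and fell in NCI-H647 against 569 for independent lists, and 172 did the reverse against 557. Across genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.42 and a Spearman rho of 0.44. The lines share no control library.

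**Figure D3:**
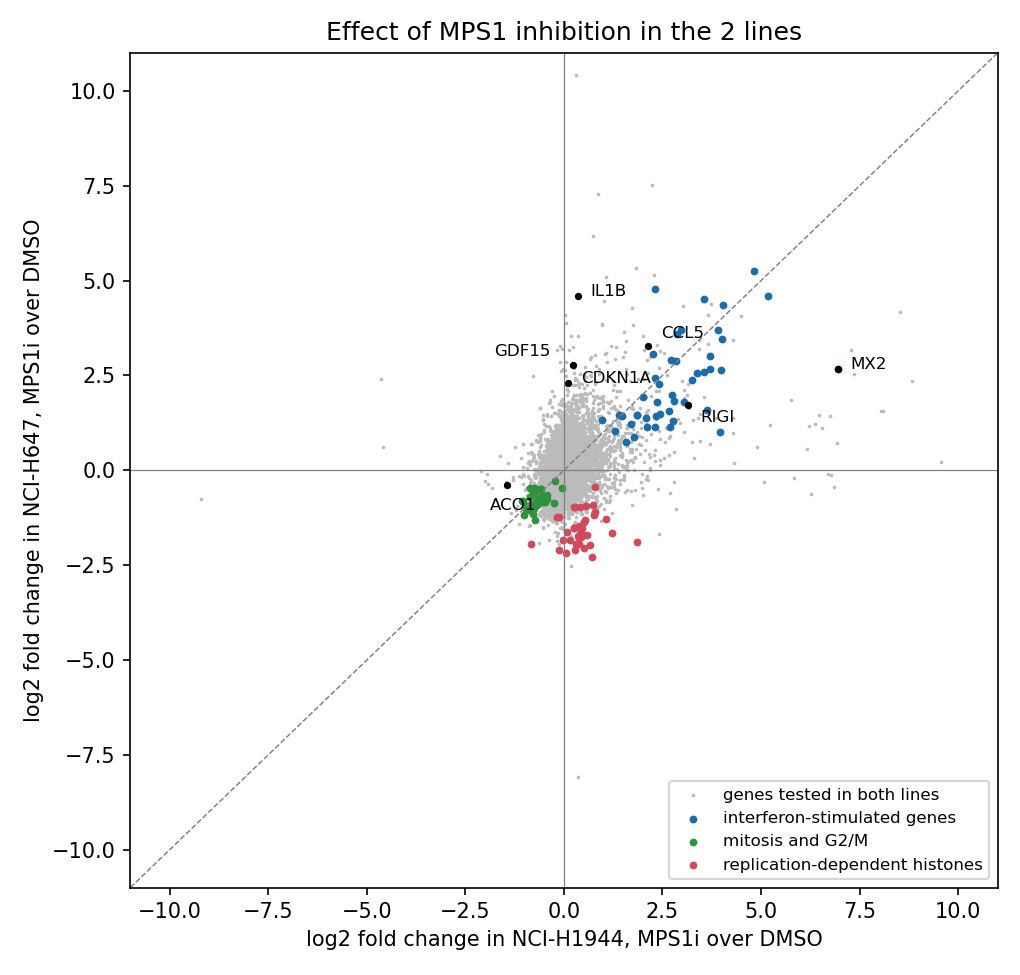
Log2 fold change (MPS1 inhibitor over DMSO) in NCI-H1944 against that in NCI-H647, 1 point per gene tested in both lines, with interferon-stimulated, mitosis and histone genes coloured. Interferon-stimulated genes lie to the upper right, mitosis genes to the lower left and histones below 0 in NCI-H647, and the positions of genes at 0 in a group depend on the prior count.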

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

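The tests of the ACO1 and RIGI spans and of the replication list were chosen only after the result was seen, as were the list tests between lines. The gene and list differences given first differed between the lines by a test of the difference itself, as the log2 change in NCI-H1944 minus that in NCI-H647. They cover 16 of 24 lists, and 63 of 78 genes taken from the naming rule and tested in both lines. Of the 63, 36 lay above 0 and 27 below. The rule took some of these genes for the size of this very difference. Most others were taken for large changes or small adjusted p within a line. The 63 of 78 is therefore a tally of selected genes and not a share of genes in general. Among all 12883 genes tested in both lines, 2663 were called above 0 and 2459 below. Where a gene was at 0 in a group, the fitted value depends on the prior count and is no bound. The fall of BHLHB9 to 0 counts in both treated NCI-H1944 libraries is uncertain, as are the readthrough loci, because how overlapping loci were counted is not given in the sources used here.

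Among interferon, sensing and antigen presentation genes the differences above 0 were GBP5 6.54, AIM2 5.44, MX2 4.29, TNFSF10 2.67, TREX1 2.23, PNPT1 1.80, CASP1 1.73, RIGI 1.42, IFIT1 1.33, IFI16 1.26, IFIH1 0.92, STING1 0.73, B2M 0.62 and TAP1 0.26. Those below 0 were MX1 -0.34, ISG15 -0.72, IFI6 -0.73, TRIM22 -0.97, CCL5 -1.12 and IFI27 -2.48. Among cytokines, secreted factors and stress genes the differences were IL7R 6.81, IGFBP6 1.10, CD68 0.61, NT5E 0.21, MDM2 0.18, IL6 -0.38, CTSL -0.52, PMAIP1 -0.64, GABARAPL1 -0.87, DNAJB9 -1.01, CXCL8 -1.14, SOD2 -1.21, PPP1R15A -1.41, CDKN1A -2.19, GDF15 -2.56, MMP1 -2.86, IL1B -4.25, LCN2 -5.44 and PI3 -6.44. In cell cycle, histone, translation and redox genes they were H3C2 2.99, H2BC12 2.18, H2AC18 1.88, AKR1B10 1.68, NQO1 0.69, ASPM 0.57, TYMS 0.56, RPL3 0.55, TKT 0.53 and PLK1 -0.25. For the remaining genes they were GPSM3 6.90, ZFP91-CNTF 6.49, NHSL2 4.09, NEXN 4.03, SLC15A3 3.91, MAP2K6 1.72, SFXN2 1.52, PWAR5 1.28, AKNA -0.90, RPL36A-HNRNPH2 -0.99, ACO1 -1.06, COMMD3-BMI1 -7.05, BHLHB9 -8.46 and ARL2-SNX15 -10.11. In 7 of these genes leaving out a library ended the call. Without the first NCI-H1944 DMSO library the adjusted p was 0.0528 for PLK1, and without the second it was 0.0723 for TAP1 and 0.0834 for RPL36A-HNRNPH2. Without the first treated NCI-H1944 library it was 0.0521 for MDM2 and 0.0537 for PWAR5, and without the second 0.0661 for TAP1, 0.0558 for PLK1 and 0.110 for RPL36A-HNRNPH2. Without the first NCI-H647 DMSO library it was 0.111 for PLK1, 0.0937 for MDM2 and 0.0616 for PWAR5, and without the second 0.385 for TAP1 and 0.0953 for TRIM22. Without the first treated NCI-H647 library it was 0.130 for TAP1, 0.0979 for MDM2 and 0.136 for PWAR5, and without the second 0.0981 for PLK1 and 0.0522 for AKNA. The difference of RPL36A-HNRNPH2 was -1.83 without the first treated NCI-H1944 library and -0.47 without the second, and that of TAP1 was 0.14 without the second NCI-H647 DMSO library. Where a lone count above 0 was left out of the NCI-H647 DMSO group, the fitted difference moved to -14.57 for COMMD3-BMI1 (without the second library) and to -10.83 for PI3 and -8.38 for LCN2 (without the first). DESeq2 did not call TAP1 (0.0629), PWAR5 (0.0532) or RPL36A-HNRNPH2 (0.289). The lowest adjusted p over the alternatives of these 7 genes were 0.0146 for TAP1, 0.0028 for PLK1, 0.00418 for MDM2, 0.00296 for AKNA, 2.14e-05 for RPL36A-HNRNPH2, 0.00272 for TRIM22 and 0.0116 for PWAR5.

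At the preset correlation the lists with a called difference were histones 1.95, interferon-stimulated genes 0.58, DNA replication 0.51, DNA sensing 0.50, MHC class I presentation 0.40, epithelial and mesenchymal state 0.32, NRF2 targets 0.22, YAP targets 0.21, RNA sensing 0.20, ribosomal proteins 0.19, cell-cycle inhibitors -0.13, lysosome -0.24, stress responses -0.31, NF-kB targets -0.32, cytokines -0.35 and secreted factors of senescence -0.41, as medians over genes. With an estimated correlation only interferon-stimulated genes (adjusted p = 0.0442) and DNA replication (0.0295) passed, and histones, for example, had an adjusted p = 0.0559 with an estimated correlation.

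ACO1 fell 2.73-fold in NCI-H1944 while RIGI, its tail-to-tail neighbour on chromosome 9, rose 8.81-fold. In the NCI-H647 table on GRCh38, ACO1 spans 32384603 to 32454769 on the plus strand and RIGI starts at 32455302 on the minus strand, so the annotated spans are 532 bp apart and shared reads of overlapping spans are argued against. A general lowering of genes that face a strongly raised neighbour was argued against too, since 23 such partners of 200 protein-coding genes with coordinates raised at least 4-fold had a median log2 change that differed from that of other genes by -0.0148 (permutation p = 0.777). Of these partners, which include ACO1, 3 were called lower and 5 higher. The raised genes needed no level beyond the count filter, so a lowering only beside highly expressed ones is not excluded. In NCI-H647, where RIGI rose 3.29-fold, ACO1 fell 1.31-fold. An effect of the treatment on ACO1 itself, or an effect at this locus alone, for example by RIGI transcripts that run past their annotated end, may remain and was not tested.

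Histone genes fell in NCI-H647 (median -1.74) and rose in 14 of 36 in NCI-H1944. Their summed level in DMSO libraries was 31.5 times higher in NCI-H647 (14612 against 463 CPM), as poly(A) selection in the other line would give, so the NCI-H1944 libraries may see only a small tailed part of these mRNAs. After thinning all NCI-H647 libraries to equal depth the median was -1.75. Thinning keeps each gene's expected share of its library, so this median could hardly move. The thinning therefore does not decide whether the lower depth of the treated NCI-H647 libraries played a part. A smaller share of cells in S phase in treated NCI-H647 cultures is a candidate explanation for the fall, since the replication list was lower there by a median 0.51, a value already known when that test was chosen. Line and kit change together, so a difference of the lines themselves stays open.

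Readthrough loci held 4 of the 8 largest falls by the naming rule in NCI-H1944. Over 104 such loci the median difference between replicates of a group was 0.56 log2 CPM against 0.21 for genes of matched expression, a ratio of 2.67, and 15 loci were higher and 11 lower. Reads may be split unevenly between a locus and its component genes, as CNTF, with 42 and 48 counts after DMSO and 0 and 0 after the inhibitor, against 0 and 0 then 75 and 97 for ZFP91-CNTF, also suggests. COMMD3-BMI1, at 369 and 385 against 19 and 14 counts, differed by far more than its replicates, and no biological explanation for it was tested.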

How the results depend on the processing

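The tests on protein-coding genes alone and on thinned libraries were chosen after seeing the data. Among the genes taken from the naming rule, the printed gene differences and the lists within each line, no call reversed under the alternatives run. The signs of the other called genes were not compared one by one, and the list tests between the lines had no such alternatives. Apart from the 1.5-fold minimum, 52 of 55 genes taken from the naming rule in NCI-H1944, 55 of 57 in NCI-H647 and 56 of the 63 printed gene differences between lines kept their call under every alternative run for them. The exceptions were CGAS, MSH5-SAPCD1 and RPL36A-HNRNPH2 in NCI-H1944, CGAS and STING1 in NCI-H647, and the differences of TAP1, PLK1, MDM2, AKNA, RPL36A-HNRNPH2, TRIM22 and PWAR5. Most of the genes tallied were picked for large changes or small adjusted p in the main fit, which favours a kept call. The tally therefore does not describe the other called genes, whose totals moved more, as given next. Against the 1.5-fold minimum 12 and 5 named genes were not called, among them TTK, MAVS and CDKN1A in NCI-H1944 and MAVS in NCI-H647, and the totals were 385 higher and 42 lower in NCI-H1944 and 792 and 464 in NCI-H647, as a stricter question gives. With no low-count filter 1319 were higher and 1006 lower in NCI-H1944, and DESeq2 called 2122 and 2573 in NCI-H647. For both of these counts the cause was not tested. With an estimated correlation in camera 0 lists were called in either line (from 20 and 15), with 11 of 26 in NCI-H1944 and 9 of 24 in NCI-H647 at an unadjusted p under 0.05, and fry called 23 and 21. Beyond the main calls, fry called p53 targets, lysosome and hypoxia genes in NCI-H1944. In NCI-H647 it added DNA sensing, p53 targets, cell-cycle inhibitors, cholesterol synthesis, YAP targets and epithelial and mesenchymal state genes. The other totals lay within 1.5 times. List medians kept their sign under TMM, RLE and DESeq2 factors and protein-coding genes alone. Leaving out 1 library leaves a group with a lone library that is assumed to vary like the other group. It gave 1688 to 2050 higher and 1609 to 1682 lower in NCI-H1944, 3314 to 3677 and 3576 to 3718 in NCI-H647, 17 to 20 and 14 to 15 lists, and 2239 to 2617 and 1919 to 2351 differences between the lines. Treated and control libraries of the same replicate number showed no shared deviation (correlation of deviations 0.017 in NCI-H1944 and -0.039 in NCI-H647). No pairing was therefore detected, but whether they were prepared together is not known from the labels. With the replicate block 2490 were higher and 2327 lower in NCI-H1944, 4236 and 4198 in NCI-H647, 19 and 15 lists were called, with lung and squamous lineage in NCI-H1944 no longer among them (adjusted p = 0.0536), and the differences numbered 2675 and 2463. In NCI-H647, IFNB1 and IFNL1 were under the count minimum and not tested. Groups of 2 are too small for a count over other splits of the samples.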

Other observations

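The list tests in this part, on families chosen after the values were seen, were added only then, and the test of chromosome medians was written before its result was seen. No alternatives were run for the single members of these families, and their differences between the lines are not counted among those given above. Guanylate-binding proteins, interferon-induced GTPases of cell-autonomous defence, rose in 5 of 5 tested genes in both lines (median 3.97 in NCI-H1944, adjusted p = 1.42e-07, and adjusted p = 0.124 with an estimated correlation, and 1.15 in NCI-H647, 4.98e-05, and adjusted p = 0.115 with an estimated correlation). GBP1 rose by 3.97 ± 0.10 and 1.01 ± 0.05 in NCI-H1944 and NCI-H647, and GBP4 by 4.29 ± 0.27 and 1.39 ± 0.09. Immediate-early transcription factors rose in 13 of 15 genes in NCI-H1944 (median 0.86, 4.69e-12, and adjusted p = 0.139 with an estimated correlation) and 14 of 15 in NCI-H647 (median fold 3.02, adjusted p = 9.68e-10, and adjusted p = 0.0912 with an estimated correlation). EGR1 rose by 3.05 ± 0.17 and 1.89 ± 0.06, FOSB by 2.55 ± 0.25 and 3.10 ± 0.15, and the orphan nuclear receptor gene NR4A1 by 0.37 ± 0.04 and 3.55 ± 0.11. Acute-phase and complement genes rose in 8 of 10 (median 1.16, 1.22e-10, and adjusted p = 0.124 with an estimated correlation) and 8 of 8 (median 1.91, 1.54e-08, and adjusted p = 0.0912 with an estimated correlation). SAA1, an acute-phase apolipoprotein, rose by 2.37 ± 0.28 and 3.30 ± 0.09, and CFB, complement factor B, 3.04-fold and 5.78-fold.

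Serpin B genes, intracellular protease inhibitors, rose in 4 of 8 in NCI-H1944 (median 0.40, 0.0254, and adjusted p = 0.193 with an estimated correlation). In NCI-H647 5 of 9 rose and 1 fell (median 0.44, 0.0319, and adjusted p = 0.174 with an estimated correlation). APOBEC3 cytidine deaminases rose in 3 of 6 in NCI-H1944 (median 1.09, 0.0101, and adjusted p = 0.193 with an estimated correlation), with APOBEC3B higher by 1.17 ± 0.20. In NCI-H647 1 rose and 2 fell of 5 (median 0.33 while the test pointed down, adjusted p = 0.782), with APOBEC3B at -0.44 ± 0.10. Cytosolic tRNA synthetases fell in 9 of 20 and rose in 1 in NCI-H1944 (median -0.09, 0.0048, and adjusted p = 0.161 with an estimated correlation) and fell in 12 of 20 and rose in 3 in NCI-H647 (median -0.15, 0.00659, and adjusted p = 0.153 with an estimated correlation). WARS1, the tryptophanyl synthetase, which interferon induces, rose by 0.56 ± 0.03 and 0.40 ± 0.05. Ribosome biogenesis factors fell in 4 of 20 in NCI-H1944 (median -0.03, adjusted p = 0.106, not called as a list), and in NCI-H647 10 of 20 fell and 4 rose (median -0.16, 0.0319, and adjusted p = 0.174 with an estimated correlation). MHC class II genes were not called in NCI-H1944 (2 higher of 7, median 0.83, adjusted p = 0.106), and 4 were tested in NCI-H647, too few for a list test, with 1 higher and 1 lower.

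Missegregation could have left treated cultures with net gains or losses of whole chromosomes. A shared shift of an autosome's protein-coding genes by at least 0.1 on the log2 scale was the cut-off set beforehand for that hypothesis. The largest distance of an autosome's median from that of all autosomal genes, over both lines, was 0.0802, for chromosome 4 in NCI-H647 (median -0.07 over 506 genes), so no such shift was seen. The next largest distance was 0.0750, for chromosome 20 in NCI-H647. Gains and losses that balance between cells would leave these medians in place and are not excluded. A net gain or loss in a small share of cells could shift a median by less than 0.1 and is not excluded either.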
